A study of Homo sapiens with 6 samples.

How the data were processed

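RNA of Ntera2 cells, a human embryonal carcinoma line, was measured on 6 one-channel arrays: 3 of cells labelled as untreated control and 3 of cells treated with siRNA against the zinc finger gene ZNF217. Each group carried the replicate letters A, B and C. The labels do not say whether the arrays came from separate cultures, so p-values measure the spread between these arrays, which may be technical. They name no control siRNA, time after treatment, siRNA sequence or dose, and the control arrays are described only as untreated. The labels give Cy5 as the dye.

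The deposited table held 1 linear intensity per probe and array, in 47293 rows. The values had already been background-subtracted when deposited, as seen from the 32.5% to 34.7% of intensities per array that lay below 0; the software, background method and scaling were not given in the sources used here. The 4 rows named for bacterial control genes were left out, which left 47289 probes. The array means of the control and the treated array of the same letter lay within 0.12% of each other (letter A 576.62 and 576.23, letter B 628.73 and 629.04, letter C 614.55 and 613.81). No column of the table was left unused.

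Genes were named from the platform annotation paired with the probes, with symbols looked up by gene ID in a RefSeq table of assembly GRCh38, used for names and chromosomes only. A single symbol was given for 18468 probes and none had several; 28821 probes are unnamed here. The gene ID was found for 18451 probes and no symbol changed. In all, 16225 distinct genes were named.

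Analysis used R 4.3.3 with limma 3.58.1; plots were drawn with Python 3.11.15 and matplotlib 3.10.9. The design, the named-gene rule, the gene lists and most other settings tried were set before the data were examined. Array quantiles differed by 0.366, 0.239, 0.127 and 0.146 on the log2 scale at the 50th, 75th, 90th and 99th percentile, above the 0.1 set as the limit, so the arrays were quantile normalized. Values under a floor of 32 were raised to it and log2 was taken (log2 of the floor is 5). The planned filter on probes under the 40th percentile of mean level removed nothing, because that percentile was the floor itself. Instead, the 27951 probes at the floor on all 6 arrays were left out, since they carry no spread; 19338 probes remained, 13547 of them with a symbol, for 12488 genes. Treated and control arrays were compared with limma's lmFit and eBayes, without a pairing term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This is called the unpaired fit.

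Whether the letters pair the arrays was checked before the fits were compared. Over 10434 probes with a mean log2 level of at least 7, deviations from the group means correlated by 0.51, 0.74 and 0.79 between control and treated arrays of the same letter, and by 0.066 or less, down to -0.62, between arrays of different letters. The letter held 66.5% and the treatment 21.5% of the variance of those probes. The pairing comes from the labels' letters and this check of the data; what the letters stand for was not given in the sources used here. A fit with the letter as a block was planned beside it.

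A further fit was chosen after seeing the data. It kept the letter as a block, added an offset of 50 to normalized values raised to at least 0 in place of the floor, and let eBayes use a mean-variance trend and robust estimation. It is called the paired offset fit, and its log2 differences understate the change of dim probes. In it eBayes gave 24.1 degrees of freedom to a variance pooled over probes, against 2 from a probe's own residuals. Its p-values thus rest mostly on the pooled variance. Single genes are said to have risen or fallen where they passed an adjusted p of 0.05 in this fit. A probe at the floor on every array of a group has only a bound there, and one at the floor on some arrays is bounded on those; such folds were computed with values raised to the floor of 32 and are given as at least that size.

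The named genes are ZNF217, then the 12 rises and 12 falls with the largest change among probes past the threshold whose treated arrays all lie outside the range of the control arrays. As none passed in the unpaired fit, these places were filled in order of unadjusted p, as the rule sets, and the genes so named did not pass that fit. The rule adds 12 fixed genes and up to 4 members per gene list with the lowest adjusted p. For the lists, members that passed the paired offset fit are given below instead. Most members picked by the rule that did not pass it are therefore not named. Other genes are named where they passed the paired offset fit, and were chosen after their values were seen. For genes with several probes in a gene list, the probe with the highest mean level was used.

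Gene lists were tested with camera (preset correlation 0.01), adjusted over the 33 lists, all of which had at least 5 measured members; tests with an estimated correlation and fry were planned beside it. The 28 gene lists were pluripotency factors and markers, neural, mesoderm, endoderm, trophoblast and HOX cluster genes, corepressors that bind ZNF217, neighbours of ZNF217 on chromosome 20, DNA replication, mitosis, p53 target, interferon and double-stranded RNA response, unfolded protein and integrated stress response, heat shock, immediate early, TGF-beta and BMP, epithelial and mesenchymal, WNT, NOTCH, cholesterol synthesis, glycolysis and hypoxia, histone, ribosomal protein, respiratory chain, proteasome, RNA interference, imprinted, and cancer-testis and germ cell genes. The 5 lists of markers of other cell types were fibroblast, endothelial, blood, neuron and muscle. Fisher's exact test of how many list members the paired offset fit called, per direction (66 tests), was added after seeing the data. It treats genes as independent, which they are not.

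The fits were tested on simulated treated and control arrays with 21186 probes, 50 of them changed at each of 4 sizes. The unpaired fit called 2% of probes changed 1.5-fold, 16% of those changed 2-fold, 58% of those changed 3-fold and 72% of those changed 4-fold. The paired offset fit called 64%, 76%, 98% and 100%, and 9 of its 178 calls were false. Its median log2 estimates at the 4 sizes were 0.565, 0.932, 1.49 and 1.85. Those of the unpaired fit were close, at 0.603, 0.999, 1.56 and 1.97. As the paired offset fit understates dim probes, the changed probes were mostly not dim. The rates therefore do not cover probes near the floor, such as many of the 12 rises (median control log2 5.1). They rest on simulated errors and need not hold for real arrays. With no probe changed, both fits made 0 calls. Other settings covered the scaling between arrays, the floor, the filter, the variance model, the block, array weights, the threshold, the set test, and each array left out. The number of arrays limits the precision.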

Results

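Transcript levels were compared between untreated Ntera2 cells and Ntera2 cells given siRNA against ZNF217, with 3 arrays per group. Ntera2 is an embryonal carcinoma line with features of pluripotent cells. ZNF217 encodes a zinc finger protein that recruits corepressors and is often amplified in tumours. The series title places the experiment beside a search for genes that ZNF217 regulates directly, and the arrays address which transcripts differ once its level is lowered. Mean intensity lay between 576 and 629 on the 6 arrays, and 31.5% to 32.6% of probes per array exceeded an intensity of 32.

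ZNF217 itself fell in treated cells. Its probe (NM_006526, chromosome 20) had a normalized intensity of 1252 ± 246 (SD, n = 3) in control and 504 ± 111 (SD, n = 3) in treated cells, and the means of the log2 values put the treated level at 40.1% of control. Control arrays A, B and C read 1169, 1528 and 1058, and treated arrays A, B and C read 518, 607 and 387. All treated arrays lay below all control arrays. The difference was -1.32 on the log2 scale (SE 0.22), with a limma adjusted p of 0.309 in the unpaired fit and 0.18 with the letters as a block. In the paired offset fit it was -1.24 with an adjusted p of 3.71e-08. An exact two-sided permutation test of the 6 values gave 0.1, the smallest p that 3 arrays against 3 allow.

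Beyond ZNF217, genes such as CLEC1A (at least 8.83-fold), TRIM22 (3.58-fold), SPP1 and CDKN1A (1.87-fold) rose and genes such as WNT3A, NODAL, GAD1 and SF3B2 fell in the paired offset fit. These folds are from the unpaired fit. Log2 differences of CLEC1A, TRIM22 and CDKN1A were 2.16, 1.63 and 0.90 in the paired offset fit. That limma fit, chosen after seeing the data, called 1265 probes, 741 higher and 524 lower in treated cells. Of these, 498 changed by at least 1.5-fold on the scale of that fit (322 higher and 176 lower). Counting 1 probe per gene, 641 of 12488 genes rose and 396 fell. The unpaired limma fit, set beforehand, called 0 of 19338 probes, with a smallest adjusted p of 0.0876, and had 1359 probes at an unadjusted p under 0.05 (761 higher and 598 lower). Chance gives 967 for arrays that the letters do not pair, and simulated arrays with letters and no change gave 340 of 21176. With the letters as a block and no other change it also called 0, with a smallest adjusted p of 0.18 and 2769 probes at an unadjusted p under 0.05. Limited to the 12576 probes above the floor on all 6 arrays, a paired fit with trend and robust estimation called 833 probes, of which 828 were among the 1265 and changed the same way.

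**Figure D1:**
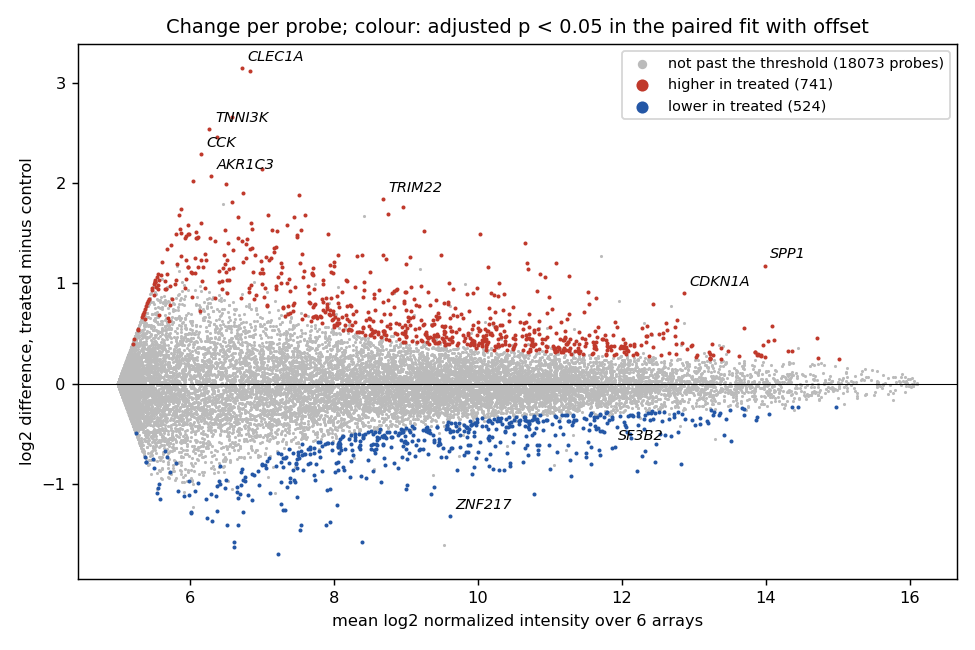
Each point is 1 of the tested probes, with its mean log2 normalized intensity over 6 arrays on the x axis and its log2 difference between treated and control cells on the y axis. Red (741 probes) and blue (524 probes) mark those past an adjusted p of 0.05 in the paired offset fit, grey the others, and ZNF217 lies at -1.32.

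Of the 12 rises named by their unadjusted p in the unpaired fit, 8 were at the floor on at least 1 control array, while the bright transcript SPP1 had an adjusted p in the paired offset fit as low as any of them (5.2e-09). CLEC1A, a C-type lectin-like receptor, went from a normalized intensity of 32.2 ± 10.6 to 326 ± 123 (SD, n = 3 each). As it exceeded the floor on 1 of 3 control arrays, its rise is given as at least 8.83-fold, against values raised to the floor. TRIM22, an interferon-inducible antiviral protein, went from 220 ± 41.4 to 781 ± 76.1, or 3.58-fold. AKR1C3, an aldo-keto reductase of steroid metabolism, was above the floor on 2 of 3 control arrays and rose at least 4.19-fold. SOSTDC1, a secreted BMP and WNT antagonist, and MCF2, a guanine nucleotide exchange factor, each exceeded it on 1 of 3 control arrays and rose at least 4.05-fold and 2.82-fold. TNNI3K, CCK, SCN9A and AKR1C1 were at the floor on all control arrays, and were at least 5.8-fold, 4.88-fold, 3.33-fold and 2.02-fold higher in treated cells. MPZL2 rose 2.3-fold, the growth factor EGF 1.94-fold and the death receptor TNFRSF10A 1.88-fold. The rule takes only genes whose arrays do not overlap, so by selection each of these 12 was higher in 3 of 3 letters. All 12 passed the paired offset fit, which uses the same arrays and so gives no independent support. Their adjusted p in that fit ran from 5.2e-09 for CLEC1A and TRIM22 to 0.011 for AKR1C1. None passed the unpaired limma fit, where their adjusted p ran from 0.0876 to 0.151, nor the fit with the letters as a block, where it was 0.18 for each. MPZL2 rests on 1 of 3 probes, the others being near the floor with differences of 0.09 and 0.09.

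Of the 12 falls named in the same way, 7 passed the paired offset fit. PWWP3A, known as a protein of DNA damage sites, went from 2078 ± 125 to 1215 ± 99.9 (SD, n = 3 each), 1.71-fold lower. The mRNA decapping factor EDC3 was 1.61-fold lower, the splicing factor SF3B2 1.55-fold, the reticulon RTN1 1.68-fold, cytochrome c (CYCS) 1.46-fold and the mitochondrial fusion protein MFN2 1.5-fold. The zinc finger gene ZNF302, above the floor on 2 of 3 treated arrays, was at least 2.42-fold lower on 1 probe, while its other 2 probes lay near the floor. In that fit these 7 genes had adjusted p from 1.37e-05 (PWWP3A) to 0.0271 (MFN2). The other 5 did not pass: AP1AR (log2 difference -0.70), HCRT (-0.88), LIG3 (-0.44 on 1 probe, -0.18 on a brighter one), and ACACB and SSTR1, which were at the floor on all treated arrays and at least 1.53-fold and 1.52-fold lower. In the unpaired limma fit the adjusted p of the 12 lay between 0.193 and 0.326.

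**Figure D2:**
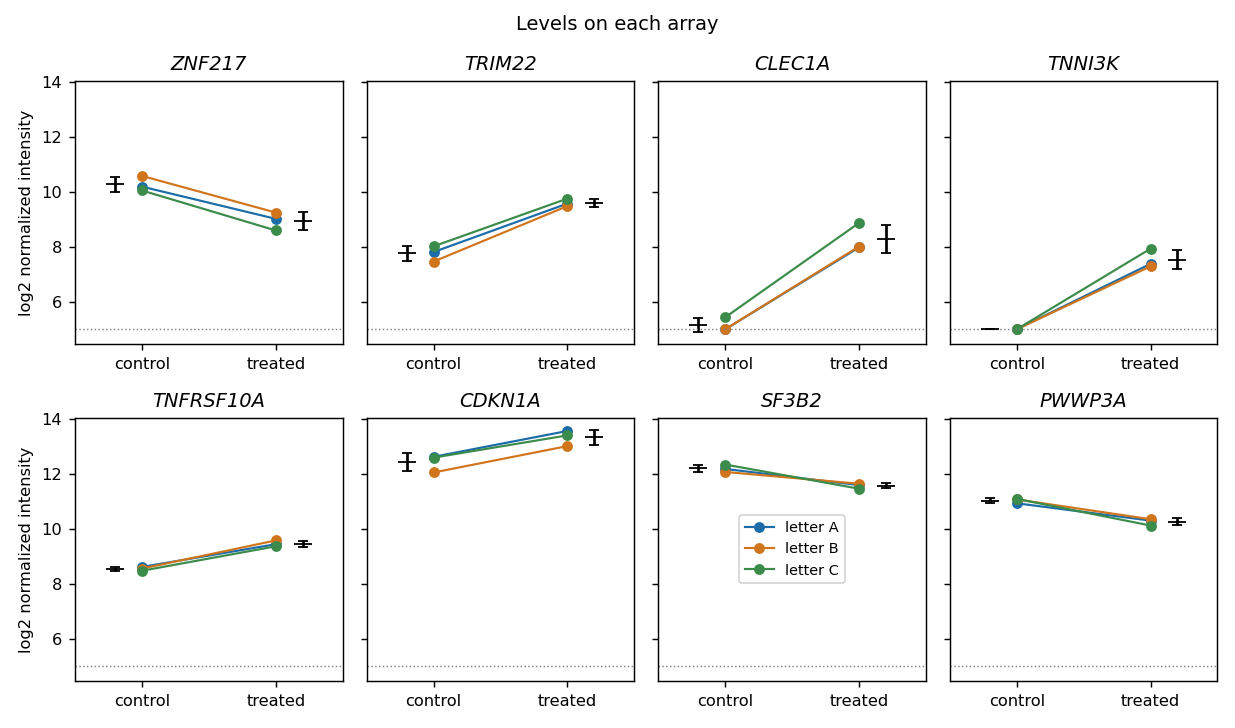
Log2 normalized intensity (y axis) of 8 genes in control and treated cells, with a line joining the arrays of the same letter, and bars for the mean ± SD of 3 arrays. ZNF217 lies lower in every treated array, TRIM22, CLEC1A and CDKN1A higher, and the dotted line is the floor at 5.

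Several genes of the WNT pathway, which patterns the early embryo, fell in treated cells. Of 22 measured members 7 fell and 0 rose in the paired offset fit, and 15 did not pass. The 7 were the target genes SP5 (log2 difference -0.93, SE 0.18), NKD1 (-0.77, SE 0.13), APCDD1 (-0.60, SE 0.11) and LEF1 (-0.48, SE 0.10), the ligands WNT5B (-0.71, SE 0.10) and WNT5A (-0.54, SE 0.10) and the receptor FZD1 (-0.36, SE 0.11). Chance placed 0.7 falling genes in a list of this size (Fisher's exact test, p = 3.5e-06, adjusted over 66 tests 0.00023). With both arrays of a letter left out, 7 fell without A, 6 without B and 5 without C, while 1, 1 and 0 rose. These counts rest mostly, and without B or C almost wholly, on the variance pooled over probes. The camera test of the whole list did not pass, with an adjusted p of 0.192 in the unpaired fit, 0.121 with the letters as a block, 0.0504 on the values of the paired offset fit, and 0.525 (0.744 with the block) with an estimated correlation. Adjusted over the list alone, 0 members passed in the unpaired fit and 7 fell with the block.

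Some mesoderm and pluripotency genes fell as well. In the mesoderm list 4 of 19 members fell in the paired offset fit: the primitive streak factors TBXT (-0.85) and MESP1 (-0.70), MSX1 (-0.71) and the ligand WNT3 (-0.75), while ACTA2, a smooth muscle actin, rose by 0.47. EOMES had the largest difference of the list in that limma fit (-1.5, SE 0.51) and was lower in 3 of 3 letters, but did not pass (adjusted p = 0.359). Among 24 pluripotency factors and markers, NODAL (-0.90), GAL (-0.67), L1TD1 (-0.39) and PODXL (-0.32) fell and CRIPTO, a NODAL co-receptor, rose (0.40). Neither list passed camera, with adjusted p of 0.269 and 0.328, and the falling members did not exceed chance after adjustment (Fisher's exact test, adjusted p = 0.086 and 0.14). The core pluripotency factors passed neither the unpaired nor the paired offset fit, and NANOG passed (adjusted p = 0.0493) with letter A left out of the latter. In the unpaired limma fit POU5F1 differed by -0.14 (SE 0.22), NANOG by 0.39 (SE 0.28), SOX2 by 0.30 (SE 0.47) and LIN28A by -0.12 (SE 0.16). SOX2 lay near the floor, at 38.2 ± 15.9 in control cells (SD, n = 3).

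The list of neuron markers was higher in treated cells by camera, while 2 of its 7 members rose in the paired offset fit (Fisher's exact test, adjusted p = 0.44). The median log2 difference was 0.44, and camera gave an adjusted p of 0.0146 (0.038 with the block). With an estimated correlation the adjusted p was 0.525. The neurofilament genes NEFL (1.10, SE 0.15) and NEFM (0.51, SE 0.10) rose in the paired offset fit, and 5 members did not pass, among them GAP43 at -0.50. Adjusted over the list alone, NEFL, NEFM and SYT1 passed in the unpaired fit. Without control array B or treated array C the adjusted p of the list was 0.136 and 0.0574, and with letter A, B or C left out of the paired offset fit it was 0.0778, 0.133 and 0.0917. Of the wider neural list of 20 genes, MAP2, which encodes a dendritic microtubule protein, rose by 1.29 beside NEFL and NEFM, while the progenitor genes SOX11 (-0.43) and NES (-0.42) fell; the list as a whole did not shift (adjusted p = 0.325), and MAP2, NEFM and NEFL passed when adjusted over the list alone.

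By camera the list of p53 targets was higher and the list of mitosis genes lower in treated cells, though 4 of 21 and 1 of 25 members passed the paired offset fit (Fisher's exact test, adjusted p = 0.26 and 0.9). In the p53 list of 21 genes the median difference was 0.21, with a camera adjusted p of 0.00327, 0.00102 with the block, and 0.525 with an estimated correlation. CDKN1A, the inhibitor of cyclin-dependent kinases, went from 5530 ± 1150 to 10310 ± 1950 (SD, n = 3 each), a 1.87-fold rise with an adjusted p of 3.98e-08 in the paired offset fit. The death receptor TNFRSF10B (0.47), PHLDA3 (0.72) and SESN1 (0.66) rose too, 17 members did not pass and 0 fell. Adjusted over the list alone, 0 members passed in the unpaired fit and 5 with the block. Of 25 mitosis genes 21 had a lower value in treated cells, with a list median of -0.11, a camera adjusted p of 0.0084, 0.038 with the block, and 0.525 with an estimated correlation. TOP2A, which encodes a topoisomerase of dividing cells, fell by 0.60 in the paired offset fit and was the only member to pass. Among 23 DNA replication genes UNG fell on its brightest probe (-0.35), while its other probes differed by -0.22 and 0.27 in the unpaired fit. The DNA replication list did not shift (camera adjusted p = 0.325). Without control array B the adjusted p was 0.136 for the p53 list and 0.331 for the mitosis list, and without treated array C it was 0.201 for the mitosis list. With letter B or C left out of the paired offset fit it was 0.259 and 0.0786 for the mitosis list, while the p53 list passed without each letter.

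The list of genes of the response to interferon and double-stranded RNA was higher in treated cells by camera, though 3 of its 24 members rose in the paired offset fit (Fisher's exact test, adjusted p = 0.5). The list had a median log2 difference of 0.52, with a camera adjusted p of 0.00327, 0.0123 with the block, and 0.525 with an estimated correlation. The RNA sensors RIGI (0.79, SE 0.16) and IFIH1 (1.17, SE 0.21) and the ubiquitin-like ligase HERC5 (0.67, SE 0.10) rose in the paired offset fit, RSAD2, another interferon-induced gene, fell (-0.66), and 20 members did not pass. Adjusted over the list alone, RIGI passed in the unpaired fit. The mean difference of the list was 0.11 in letter A, 1.0 in letter B and 0.18 in letter C. The list median was 0.329 without control array B (adjusted p = 0.136), 0.344 without treated array B (0.0527), 0.338 without treated array A (0.0172) and 0.143 with letter B left out of the paired offset fit (0.285). The 12 genes of the RNA interference machinery showed no call and no shift (adjusted p = 0.98).

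**Figure D3:**
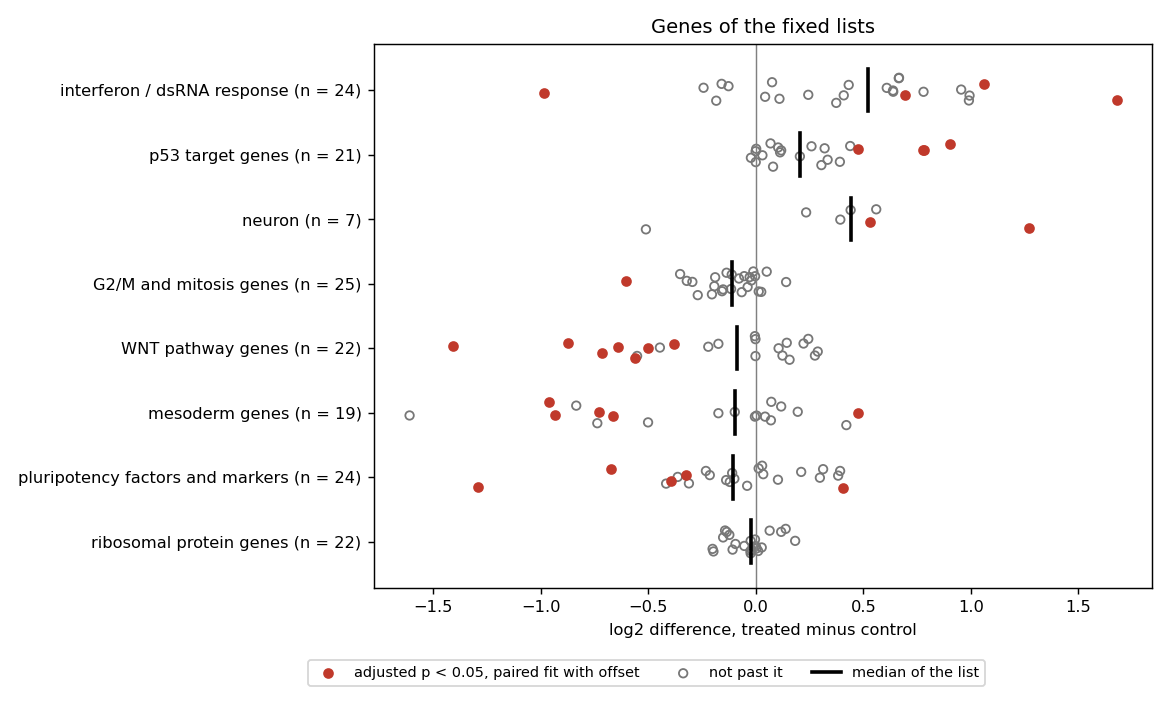
Log2 difference between treated and control cells (x axis) for each measured member of 8 gene lists (y axis), with red for members past an adjusted p of 0.05 in the paired offset fit and a bar at the list median. In the WNT list all 7 red members lie below 0, and the ribosomal protein list has none.

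Some genes for corepressors that bind ZNF217 changed. Of 16 corepressor genes HDAC1 (-0.35), RCOR2 (-0.53) and ZMYM3 (-0.36) fell and PHF21A rose (0.30) in the paired offset fit. In the unpaired limma fit KDM1A differed by -0.08 (SE 0.10) and CTBP2 by -0.01 (SE 0.11), while CTBP1 and RCOR1 lay near the floor. The list did not shift (camera adjusted p = 0.269). Among 17 neighbours of ZNF217 on chromosome 20 only ZFP64 fell (-0.68), on 1 of 3 probes, the list adjusted p being 0.499. ERBB3 (-0.43, SE 0.23), the epithelial cadherin CDH1 (0.14, SE 0.42), GAPDH (0.03, SE 0.10) and ACTB (0.01, SE 0.08) passed neither the unpaired nor the paired offset fit.

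No other developmental list shifted by camera. Among 11 trophoblast genes VGLL1 (1.10) and EGFR (0.73) rose and CDX2 (-1.04) and GATA2 (-0.49) fell (list adjusted p = 0.913), and EGFR passed when adjusted over the list alone. Among 14 HOX genes HOXC6 rose (0.62) and HOXB9 (-0.71) and HOXB2 (-0.47) fell (0.329). Of 12 endoderm genes GATA6 fell (-0.48; 0.946). Of 14 NOTCH genes DLL1 (-0.68) and RBPJ (-0.52) fell (0.328), and of 25 TGF-beta and BMP genes FST fell (-0.53; 0.328). In the list of 23 epithelial and mesenchymal genes OCLN (0.56), CLDN7 (0.45) and CDH2 (0.30) rose and MMP2 (-0.35) fell (0.343). Among 16 imprinted genes CDKN1C (-0.78) and DLK1 (-0.41) fell (0.942), and of 9 cancer-testis and germ cell genes MAEL rose (0.77; 0.325), which also passed when adjusted over the list alone.

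Lists of housekeeping and stress genes did not shift by camera and held few calls. The 22 ribosomal protein genes (camera adjusted p = 0.455) and 26 proteasome genes (0.931) held 0 calls. UQCRC2 fell (-0.30) among 22 respiratory chain genes (0.328), ASNS (-0.37) among 23 stress response genes (0.942) and INSIG1 (-0.59) among 18 cholesterol synthesis genes (0.425). In the 18 heat shock genes CRYAB rose (0.86) and HSPD1 fell (-0.23; 0.269). ADM (0.54), ENO2 (0.35) and PFKP (0.30) rose and ALDOC (-0.38) fell among 23 glycolysis and hypoxia genes (0.219). CCN2 (0.57) and IER3 (0.36) rose among 18 immediate early genes (0.662), and H2BC12 (0.60) and H4C14 (0.38) among 18 histone genes (0.334).

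Markers of other cell types did not shift apart from the neuron list. Of 8 endothelial markers ESAM (0.96) and TEK (0.60) rose (camera adjusted p = 0.325). Of 10 fibroblast markers S100A4 rose (0.55) and COL5A1 fell (-0.37; 0.488). CD53 rose (0.89) among 7 blood cell markers (0.913), and ACTA2 rose (0.47) among 6 muscle markers (0.947).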

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

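Fits that join the letters as a block with an offset or a trend, the filter on probes above the floor on all 6 arrays, the scalings over detected probes, the letters left out, the test of dim probes in the unpaired fit, and the tests of splits for adjusted and unadjusted counts were chosen after seeing the data; the others were planned. The unpaired limma fit called 0 probes and did so under 23 of 31 alternatives, including the planned paired fit (replicate block alone), which changed no call. A floor of 16 gave 4 calls, all higher, the offset with trend and robust but no block 4, all higher, and an adjusted p under 0.1 gave 1, higher. The paired offset fit gave 1265 (741 higher, 524 lower), the paired fit with trend on probes above the floor on all 6 arrays 833 (508 and 325), and the paired offset fit without letter A 1562 (938 and 624), without B 858 (481 and 377) and without C 838 (484 and 354). Of those, 1042, 714 and 695 were among the 1265 with the same direction. Leaving out single arrays gave 0 throughout. Probes at an unadjusted p under 0.05 numbered 2769 with the block, 3569 in the paired offset fit, 2928 with block and trend, 2798 with block and offset, 2880 on probes above the floor on all 6 arrays, and 3579, 2778 and 2711 without letters A, B and C. ZNF217 was lower under all 29 alternatives; it passed in the paired offset fit (-1.236), the paired fit on probes above the floor (-1.319) and without letters A (-1.304), B (-1.214) and C (-1.191). Of the 4 gene lists past the threshold, 0 remained with an estimated correlation or fry, 1 without letter B and 2 without letter C in the paired offset fit, and 0 to 4 when single arrays were left out. The 12 named rises, 12 named falls and 12 fixed genes kept their direction in 984 of 1007 combinations with an alternative and passed in 87. Median centring over all probes equals the values as deposited, because the median is the floor, and so tests nothing.

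The jump in calls between fits was weighed as a pattern. The variance pooled over probes counted for 1.79 degrees of freedom with the block alone and for 24.1 in the paired offset fit. Simulated arrays without change gave the paired offset fit 0 calls, but as real errors may differ, this cannot weigh false calls. Their share stays open: exchanging the groups within a letter gave 0 calls against 1265. But this puts the treatment difference into the residual (274 to 525 probes at an unadjusted p under 0.05, 967 by chance), so few were to be had. Of the 4 ways to place 1 array of each letter on each side, 1 gave as many as 1265 and the highest other gave 0, too few splits for a share under 0.05. Dim probes with little spread could hold down the paired fit with trend, which called 0 of all tested probes and 833 of those above the floor on all 6 arrays. They are not the whole cause of the 0 calls in the unpaired fit, which called 0 on those brighter probes too, with a smallest adjusted p of 0.239. In simulated data the unpaired fit called 2% of probes changed 1.5-fold and 16% of those changed 2-fold. Among all 10 splits of the arrays, 10 gave as many adjusted calls as the real one (0, highest other 0), and 4 as many at an unadjusted p under 0.05 (1359, highest other 2354); 10 splits allow no share under 0.05. The split with 2354 puts control A, control C and treated C together and so follows the letters. The 3 besides the real one that part all letters gave 264, 283 and 376, and simulated arrays with letters and no change 340 of 21176. Those 3 splits exchange the groups within 1 letter. A true treatment difference would widen the spread within their sides, so their low counts cannot serve as a chance level.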

Other observations

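The tests of the letters, of the double-stranded RNA explanation and of the splits for rises against falls were chosen after the results were seen, as were all gene groups tested here, the cyclic loess over detected probes and the median centring over them; the genes in the next 2 paragraphs were chosen after their values were seen.

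Among the largest falls in the paired offset fit, the ligand WNT3A fell by 1.07 on the log2 scale (adjusted p = 1.17e-05), the homeobox gene CDX1 by 1.18 (8.2e-05) and the NODAL co-receptor CFC1 by 0.94 (3.2e-05). In the unpaired limma fit WNT3A differed by -1.37 (SE 1.13, unadjusted p = 0.273) and CDX1 by -1.7 (SE 1.23, 0.221). The falls of WNT3A and CDX1 thus rest on the paired offset fit. GAD1, which makes the transmitter GABA, fell on each of 3 probes, by 1.06, 1.01 and 0.88. COL6A2 (-1.10), COL9A2 (-0.94), COL8A2 (-0.85), COL2A1 (-0.83) and NID1 (-0.88) fell, while COL8A1 rose (1.48); collagens were not tested as a group.

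Large rises included the cytokine IL1A (2.03, adjusted p = 4e-08), the protease MMP10 (2.19, 0.021), the eye and pituitary homeobox gene SIX6 (1.88), the neuroendocrine factor INSM1 (1.58) and FEZ1, a protein of axon growth (1.16). Among bright transcripts the secreted phosphoprotein SPP1 rose by 1.17 from a log2 level of 13.40 and ARHGDIB by 1.17 from 10.48. The peptide transporter TAP1 (1.21) and PLAAT4 (1.17), both interferon-inducible, rose as well.

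The 4 groups suggested by such genes were tested with limma's camera on members whose values had not been singled out, in the unpaired fit and with the block. The larger p-value of the 2 was 0.0062 for antigen presentation, 0.18 for inflammatory cytokines and proteases, 0.36 for NRF2 targets and 0.61 for further WNT genes. Antigen presentation genes, prompted by TRIM22 and TAP1, were higher in treated cells (adjusted p = 0.025 over the 4 groups, median log2 difference 0.23 over 16 genes), though with an estimated correlation the unadjusted value was 0.061 and 0 of the 16 passed the paired offset fit. The list of inflammatory cytokines and proteases left out 5 measured genes that had been seen to rise, IL1A, CXCL6, MMP10, SPP1 (1.17) and PTX3 (1.09). Its other 22 did not shift as a group by camera (adjusted p = 0.36). Of these 22, 5 rose (IL6, CCL2, NFKB1, PLAU and PTGS2) and 3 fell (SOD2, IL11 and TNFAIP2) in the paired offset fit. Over all 12488 genes 641 rose and 396 fell, and the counts in this group were not tested. NRF2 targets beyond AKR1C1 and AKR1C3 did not shift (adjusted p = 0.48, 19 genes), and NQO1 rose. Without WNT3A, CDX1, CDX2 (-1.04) and WNT3 (-0.75), which had been seen to fall, further WNT ligands, regulators and targets did not shift down (adjusted p = 0.61, 30 genes), with WNT10B and NOTUM falling and FZD6 and RNF43 rising.

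The higher interferon list could have technical sources. Between-array scaling as the whole source is argued against, as the list median stayed at 0.396 or more under 4 other scalings. An interferon level shared by both arrays of a letter cancels by design, but a difference confined to 1 letter stays open: the list mean was above 0 in every letter but as low as 0.105, and the mean over letters, 0.43, was below its SD of 0.50. A response to double-stranded RNA or transfection cannot be told apart from loss of ZNF217, because 0 control arrays are said to have received another siRNA. Lists past the threshold numbered 4 in the real split, 2 of 10 splits gave as many and the highest other gave 5. The 3 besides the real one that part all letters gave 1, 0 and 1. They exchange the groups within 1 letter, which dilutes a true difference, so these counts are no chance level. With 10 splits no share under 0.05 is possible.

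Among probes whose treated and control arrays do not overlap (1903, or 9.84% of those tested, where chance gives 10% for arrays that the letters do not pair), 159 differed at least 2-fold, and 131 of these were higher and 28 lower in treated cells. Noise near the floor is argued against: among those with a mean log2 level of at least 7, 86.9% were higher (exact 95% interval 75.8% to 94.2%). That interval treats probes as independent, which they are not, and does not measure the spread between arrays. The noisiest array, treated A, is argued against as well, as 80.5% were higher without it. Scaling stays open: the planned cyclic loess gave 46.6%, though its curve through values tied at the floor moved some by 1.95 on the log2 scale, while the values as deposited gave 86.4%, centring over detected probes 84.3% and loess over detected probes 83.4%, and a floor of 16 gave 67.8%. Of the 10 splits, 2 put as many 2-fold probes on a side as the real 131 (highest other 158, in the split that follows the letters), while the 3 besides the real one that part all letters gave 3, 7 and 6; these are too few splits for a share under 0.05.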
